A study of Mus musculus with 91 samples.

How the data were processed

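Per the labels, RNA was taken from mouse embryonic stem cells grown on plates coated with embryonic fibroblasts, and libraries were made with QuantSeq, which primes on poly(A) tails and reads 3' ends. Reads were aligned with STAR 2.5.4b to GRCm38/mm10, per the submitters' processing notes, which also name featureCounts and Subread 2.0.0. The deposited values are whole-number counts of reads per gene, made by the authors with featureCounts 2.0.2 and Ensembl release 97, per the file headers. The headers show no option for strand or for reads with several matches. Reads were thus counted without regard to strand, and a gene and its overlapping antisense partner cannot be separated. Symbols were matched from the annotation for 55394 of 55573 gene identifiers. No unit other than counts was used, and CPM were computed here, by library totals or, for means given with ± and WT values set against them, by totals scaled with TMM factors.

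The 91 samples were grouped by their titles. The 16 R1 files were compared by a chi-square test of their counts and summed to 6 libraries. The 3 libraries under 100000 counts were left out. Each experiment was fitted on its own with edgeR 4.0.16 in R 4.3.3, with TMM factors, filterByExpr by group and the quasi-likelihood test. All groups of an experiment stood in 1 fit and share the estimate of the spread. The p-values were adjusted by the Benjamini-Hochberg method over the genes tested, and genes under 0.05 were called. The standard error of a log2 fold change is its size divided by the square root of the F statistic. Knockout was compared with WT as the mean over both lines or both clones, and isoforms were compared by the difference of their changes. Induction over 4 h was the change of the knockout clones less the change of WT cells over the same hours. The labels do not show whether these WT cells hold the transgene. The slope of the addback change on the knockout change used the knockout change of the other line, so that both values share no library. Its scale is the slope of the line's own knockout change on that of the other line, a value added after the slopes were seen. Common dispersion gave a coefficient of variation between libraries of 0.147 in R1, 0.227 in the 24 h experiment, 0.0363 and 0.141 in the SETa and SETb time courses and 0.335 on overexpression.

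The genes named were set by a rule fixed before the data were examined, as were the gene lists, the designs and 144 of the alternatives. The rule takes, per comparison, the 8 largest rises and 8 largest falls by log2 fold change among called genes. These had at least 10 CPM in a group mean, libraries of the compared sides that do not overlap (not asked of differences of changes) and no clone, Gm or pseudogene name. The rule adds up to 4 members of smallest p of each gene list described, or 2 where none was called. It also adds the 3 genes of smallest p where a comparison gave no call, and a fixed set of pluripotency, p53, Wnt and lineage genes where their list is spoken of. Some genes that the rule takes are not reported here. The 28 lists held 525 genes, with markers of fibroblasts and of other lineages among them. They were tested with camera in limma 3.58.1 (correlation preset at 0.01, log CPM with a prior count of 3) and again with an estimated correlation, adjusted over the lists. Folds against a group with no count were set against 3 counts over the libraries of that group, and cover counting error only. Set and Gm9531 were compared by shared words of 25 bases in the reference transcripts.

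The tests were checked on simulated counts with 200 genes changed by known folds. In them 2-fold changes were called in 32% and 4-fold changes in 86% of genes for SETa loss in R1, 50% and 83% for SETa addback, 53% and 72% for SETa induction, and 17% and 63% for SETb overexpression. Alternatives were RLE size factors, no filter on low counts, DESeq2 1.42.0, a replicate block, only the compared groups in the fit, low-depth libraries put back, single lines, clones and times, and each library left out in turn. After the data were seen 21 alternatives of 9 kinds were added. They leave out libraries that stand apart, take 1 h as the baseline or as the time of the knockout comparison, count calls off named chromosomes, or add the fibroblast share as a covariate. Shared WT libraries of R1 were simulated 20 times, and up to 100 other splits of the libraries were drawn. The data were handled with data.table (version 1.17.8) and pandas 2.3.3 in Python 3.11.15, and plots were drawn with matplotlib 3.10.9.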

Results

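SET is a histone chaperone and an inhibitor of protein phosphatase 2A. Its gene, Set, lies on mouse chromosome 2 (30057378 to 30072577 in build GRCm38/mm10) and gives 2 protein isoforms, SETa and SETb, which differ at the start of the protein. The data are 91 sets of gene counts from mouse embryonic stem cells in 5 experiments. All were made with QuantSeq, which reads the 3' ends of polyadenylated RNA. In R1 cells, an embryonic stem cell line, WT cells were set beside a knockout of SETa and a knockout of SETb, with 2 libraries per group. The other 4 experiments used KH2 cells, embryonic stem cells in which doxycycline, an antibiotic that acts as a chemical switch, turns on a transgene placed beside Col1a1. In the 24 h experiment a SETa line and a SETb line each gave WT cells, SET knockout cells, and knockout cells after 24 h of doxycycline, which returns 1 isoform to cells that lack SET (addback). Each of these groups had 3 libraries, except SETb addback with 2. A SETa and a SETb time course followed WT cells and 2 knockout clones at 0, 1, 2 and 4 h of doxycycline, with 1 or 2 libraries per group. In the overexpression experiment cells with their own SET received SETa or SETb for 24 h, with 3 libraries per group.

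Total counts per library ran from 368270 to 1111486 in R1 cells, 528005 to 8025224 in the 24 h experiment, 4139935 to 12063823 in the SETa time course, 4791204 to 37352955 in the SETb time course and 9249497 to 20482068 on overexpression. Before the data were examined, libraries under 100000 counts were set to be left out. These were WT at 0 h and clone 2 at 2 h of the SETa time course, and SETa overexpression, 1 library each. The 16 R1 files were counted as 6 samples, because files of 1 library differed by no more than sampling noise (chi-square per degree of freedom 0.968 to 1.06 in 15 pairs, against 1.59 to 2.37 in 21 pairs of different libraries). The p-values measure only the spread between these samples, which may be technical. A value after a gene name is its log2 fold change ± standard error, and rose or fell is used for genes with an adjusted p under 0.05.

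**Figure D1:**
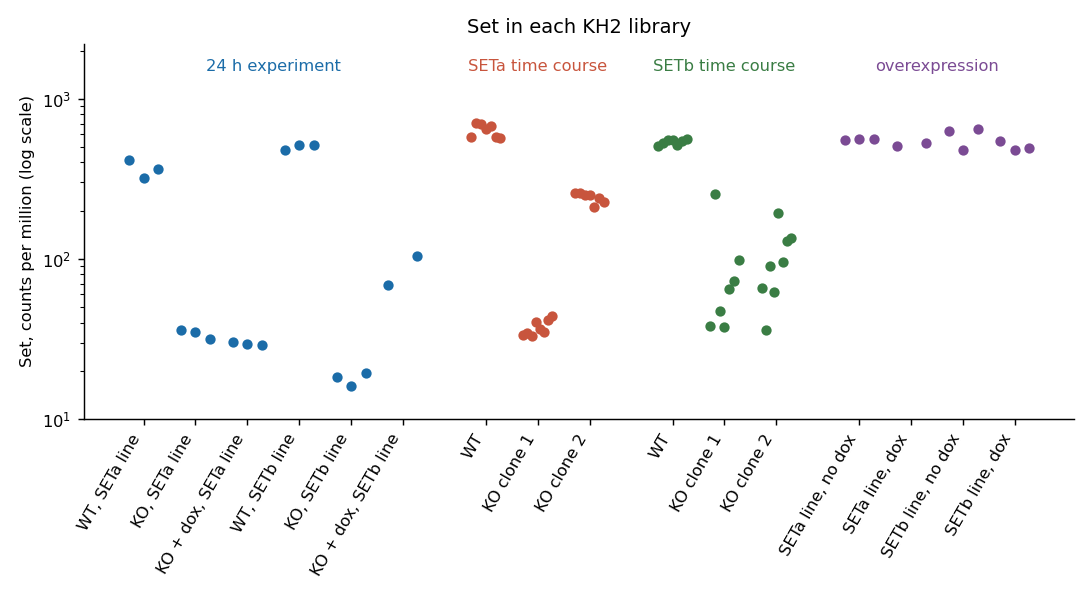
Set in every KH2 library, as CPM, the count scaled to a library total of 1000000. In the 24 h experiment it was 482 to 515 CPM in WT libraries and 16 to 19.4 CPM in knockout libraries of the SETb line.

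Set itself fell in the KH2 knockouts. In the 24 h experiment it was 322 to 417 CPM in WT and 31.5 to 35.7 CPM in knockout libraries of the SETa line, and 482 to 515 against 16 to 19.4 CPM in the SETb line (Set (log2 fold change -4.19 ± 0.12), 6 libraries against 6, adjusted p = 1.2e-13). After addback it stayed at 29.1 to 30.1 CPM with SETa and reached 68.5 to 105 CPM with SETb (Set (log2 fold change 2.33 ± 0.17), 2 libraries against 3, adjusted p = 1.47e-06). In the SETa time course at 0 h Set was 33.2 to 34.2 CPM in clone 1 but 256 to 259 CPM in the libraries labelled knockout clone 2, against 578 CPM in WT. In the SETb time course the library labelled clone 1, 0 h, replicate 2 held 254 CPM and the library labelled clone 2, 2 h, replicate 1 held 193 CPM, while clone 1 replicate 1 at 0 h held 38.2 CPM. In R1 cells Set was 1065 to 1237 CPM in WT, 679 to 682 CPM in the SETa knockout and 814 to 879.6 CPM in the SETb knockout. The 3' reads of both isoforms fall in shared sequence, so these R1 values check neither knockout.

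**Figure D2:**
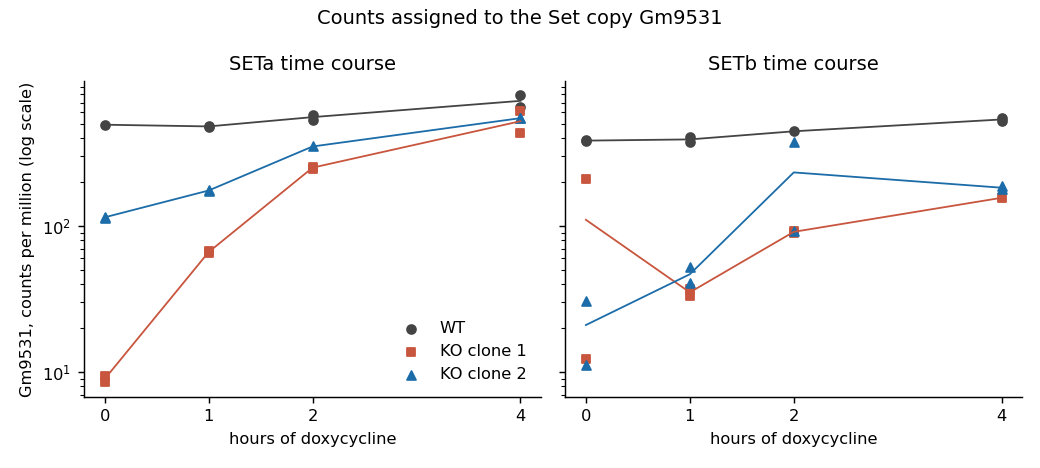
Counts assigned to Gm9531, in CPM, along both time courses. In clone 1 of the SETa time course the mean went from 8.98 CPM at 0 h to 522 CPM at 4 h.

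The transgenes were read mostly as Gm9531, a processed copy of Set on chromosome 9 (81677598 to 81678677). Of the 25-base words in its 2 transcripts, 96.4% and 100% also occur in Set, so reads of Set, of a transgene and of Gm9531 are uncertain between the 2 genes. Counts on Gm9531 rose after 24 h of doxycycline from 7.35 to 9.08 to 262 to 273 CPM in the SETa line (Gm9531 (log2 fold change 5.04 ± 0.41), 3 libraries each, adjusted p = 6.45e-06). They rose from 6.0 to 17.5 to 139 to 259.7 CPM in the SETb line (4.15 ± 0.41, adjusted p = 6.6e-05). In the SETa time course clone 1 went through 8.98, 66.3, 251 and 522 CPM at 0, 1, 2 and 4 h. Gm9531 held 424 to 486 CPM before and 685 to 687 CPM after SETa overexpression (0.56 ± 0.10, adjusted p = 1, not called), and 356 to 487 before and 555 to 567 CPM after SETb overexpression (0.54 ± 0.09, adjusted p = 0.00393).

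Few genes were called in the SETa knockout of R1 cells (2 libraries against 2). Arl14epl, with no count in WT, was at least 12.5-fold higher. H19, an imprinted RNA that does not code for protein, rose from 0.627 ± 0.887 to 55.9 ± 18.1 CPM (H19 (log2 fold change 6.09 ± 0.73)). Hal, which breaks down histidine, rose as well (4.25 ± 0.63), as did Steap3 (2.10 ± 0.38) and Nab1 (2.08 ± 0.36), a corepressor of Egr proteins. Genes of germ cells were among the largest rises: Stk31 (log2 fold change 3.10 ± 0.58) and Smc1b (2.31 ± 0.35), the latter a cohesin subunit of meiosis, and Meioc, needed for meiosis (2.04 ± 0.34). The falls were Snord13 (log2 fold change -1.87 ± 0.32), Uap1l1 (-1.74 ± 0.32), Cbr3 (-1.51 ± 0.28), Ina (-1.38 ± 0.21) and Dnmt3b (-1.16 ± 0.19), the last a DNA methyltransferase that marks formative cells (adjusted p at most 0.0358 over these genes). Tbx3, a naive pluripotency factor, rose from 162 ± 13.1 to 363 ± 46.5 CPM (1.17 ± 0.20). Crabp1, which binds retinoic acid, rose too (1.76 ± 0.31).

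Germline genes had higher values: of 14 measured germline genes, 2 rose, 0 fell and 12 were not called (8 rose and 0 fell adjusted over the list alone, adjusted camera p = 3.34e-10, adjusted p = 0.128 with an estimated correlation). Primitive endoderm markers had lower values, with Apoe (log2 fold change -1.28 ± 0.27) and Dab2 (-1.32 ± 0.28) (adjusted p at least 0.0648). Of 13 measured primitive endoderm markers, 0 rose, 0 fell and 13 were not called (0 rose and 4 fell adjusted over the list alone, adjusted camera p = 2.1e-05, adjusted p = 0.172 with an estimated correlation). Fibroblast markers leaned up without a call, with Acta2 (log2 fold change 1.48 ± 0.51): of 8 measured fibroblast (feeder layer) markers, 0 rose, 0 fell and 8 were not called (0 rose and 0 fell adjusted over the list alone, adjusted camera p = 0.00102, adjusted p = 0.221 with an estimated correlation). In all 17 genes rose and 5 fell of 9141 tested. Steap3 and Nab1 lie on chromosome 1, and off it and the chromosome 14 segment 15 genes were called. Without SETa knockout library 1 the calls were 6 and without library 2 they were 1, and DESeq2 called 13.

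Loss of SETb in R1 cells gave more calls, with naive factors among the rises and formative genes among the falls (2 libraries against 2). Calls do not rank the effects: chromosome 1 had similar medians in both knockouts but more calls here. Klf5 rose from 713 ± 47.9 to 1992 ± 325 CPM (Klf5 (log2 fold change 1.48 ± 0.17)), with Tfcp2l1 (1.55 ± 0.19), Tbx3 (1.18 ± 0.19) and Nanog (1.10 ± 0.18), all factors of naive pluripotency. Otx2, which drives the exit to the formative state, fell from 204 ± 32.6 to 40.1 ± 2.37 CPM (-2.32 ± 0.23), with the DNA methyltransferases Dnmt3b (-1.34 ± 0.19) and Dnmt3a (-1.50 ± 0.22) and with Zic5 (-1.95 ± 0.29). Lef1, through which Wnt acts, fell (-2.96 ± 0.30), as did Sema6a (-4.28 ± 0.91) and Efnb2 (-3.99 ± 0.74). Nodal, a ligand of the Activin type, rose (1.51 ± 0.30). Other falls were Aass (log2 fold change -3.90 ± 0.66), Rims4 (-3.38 ± 0.77), Snora30 (-3.18 ± 0.59) and Crb3 (-3.02 ± 0.65). Arl14epl was at least 15-fold higher than in WT, and Hal rose again (4.61 ± 0.59). Other rises, uneven between knockout libraries, were S100a8 (log2 fold change 4.24 ± 0.69, 23.5 and 124.5 CPM), Csf3r (4.02 ± 0.73) and Retnlg (3.94 ± 0.83). Hr (log2 fold change 3.96 ± 0.47) and Fgf17 (3.77 ± 0.43) rose and lie at 70.6 Mb of chromosome 14, and Casq1 (3.77 ± 0.79) lies on chromosome 1 (adjusted p at most 0.0217 over these genes).

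Of 18 measured naive pluripotency genes, 6 rose, 0 fell and 12 were not called (8 rose and 0 fell adjusted over the list alone, adjusted camera p = 6.35e-05, adjusted p = 0.185 with an estimated correlation). Of 10 measured formative and primed pluripotency genes, 0 rose, 6 fell and 4 were not called (1 rose and 6 fell adjusted over the list alone, adjusted camera p = 2.55e-05, adjusted p = 0.185 with an estimated correlation), while Fgf5 was not measured. Of 14 measured germline genes, 4 rose, 0 fell and 10 were not called (6 rose and 0 fell adjusted over the list alone, adjusted camera p = 0.00128, adjusted p = 0.214 with an estimated correlation), with Stk31 (log2 fold change 3.0 ± 0.57), Tuba3a (1.71 ± 0.36), Piwil2 (2.15 ± 0.46) and Rhox13 (2.35 ± 0.58), of which Piwil2 lies in the chromosome 14 segment. Tfcp2l1, among the naive genes, lies on chromosome 1. Of the imprinted genes, Cdkn1c (log2 fold change 2.23 ± 0.27) rose and Meg3 (-1.11 ± 0.18) fell. Replication genes Mcm6 (log2 fold change 1.12 ± 0.19) and Mcm3 (0.77 ± 0.16) and the cell cycle kinase Cdk1 (1.02 ± 0.19) rose, of which the first 2 lie on chromosome 1. The pluripotency genes Sox2 (log2 fold change 0.08 ± 0.16), Klf4 (-0.02 ± 0.18), Zfp42 (-0.21 ± 0.20), Esrrb (0.14 ± 0.22) and Pou5f1 (0.08 ± 0.39) were not called (adjusted p at least 0.714), nor were the p53 targets Cdkn1a (log2 fold change 0.13 ± 0.31) and Mdm2 (0.07 ± 0.19). In all 239 genes rose and 89 fell of 9141. Without WT library 1 the calls were 210, without SETb knockout library 1 126, by DESeq2 105, and off chromosome 1 and the chromosome 14 segment 218.

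**Figure D3:**
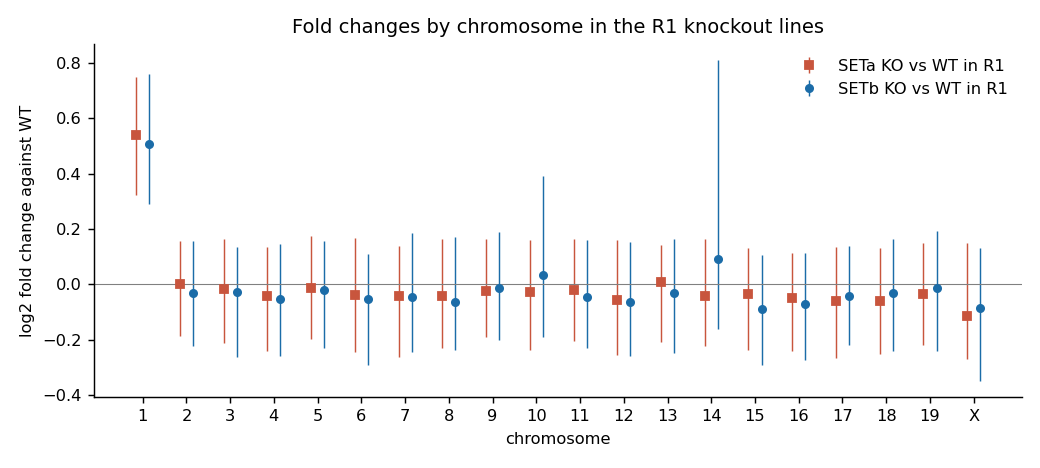
Median and quartiles of log2 fold change by chromosome in the R1 knockouts. Chromosome 1 had a median of 0.540 in the SETa and 0.508 in the SETb knockout.

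Set beside each other, the R1 knockouts differed at formative genes and in 1 segment of a chromosome, among others (2 libraries against 2). Otx2 was higher in the SETa knockout (388 ± 7.04 CPM) than in the SETb knockout (40.1 ± 2.37 CPM, log2 fold change 3.25 ± 0.23). So were H19 (6.03 ± 0.74), Dnmt3a (1.69 ± 0.22), Zic5 (1.97 ± 0.30), Lef1 (2.26 ± 0.33), Egr1 (1.62 ± 0.26), Krt18 (2.30 ± 0.53), Mycl (2.28 ± 0.53), Rny1 (1.85 ± 0.39) and Plac8 (1.77 ± 0.33). Egr1 is an immediate target of FGF signalling. Lower in the SETa knockout were Klf5 (-1.38 ± 0.17), Gbx2 (-1.54 ± 0.29) and Tfcp2l1 (-0.84 ± 0.19), the Nodal genes Nodal (-1.72 ± 0.34) and Lefty1 (-1.16 ± 0.21) and the growth inhibitor Cdkn1c (-2.41 ± 0.29). Also lower were Nkx6-3 (-4.73 ± 0.81), Serpinb6c (-4.25 ± 0.85), Myo1f (-2.94 ± 0.37), Smpd2 (-2.65 ± 0.60), Hr (-4.52 ± 0.56), Fgf17 (-4.10 ± 0.48), Dmtn (-3.35 ± 0.23) and Nudt18 (-2.83 ± 0.58), of which the last 4 lie in the chromosome 14 segment (adjusted p at most 0.0477 over all genes named here). Of 10 measured formative and primed pluripotency genes, 3 rose, 0 fell and 7 were not called (4 rose and 2 fell adjusted over the list alone, adjusted camera p = 0.00216, adjusted p = 0.254 with an estimated correlation). Of 18 measured naive pluripotency genes, 0 rose, 3 fell and 15 were not called (0 rose and 6 fell adjusted over the list alone, adjusted camera p = 0.00906, adjusted p = 0.254 with an estimated correlation). Nodal and BMP targets leaned lower: of 12 measured Nodal and BMP target genes, 0 rose, 2 fell and 10 were not called (0 rose and 4 fell adjusted over the list alone, adjusted camera p = 0.0864, adjusted p = 0.353 with an estimated correlation). In all 26 genes were higher and 85 lower in the SETa knockout. Without SETa knockout library 2 the calls were 36, by DESeq2 67 and off chromosome 1 and the segment 66.

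On chromosome 1 most genes were higher in both R1 knockouts. The median log2 fold change was 0.540 in the SETa and 0.508 in the SETb knockout over 386 genes of at least 5 log2 CPM. Chromosome 1 held 6.46 to 6.54% of counts in WT, 9.06 to 9.38% in the SETa and 8.75 to 9.18% in the SETb knockout libraries. Between 62 and 88 Mb of chromosome 14, 54 of 91 genes rose in the SETb knockout (median 1.37), against 0 in the SETa knockout (median 0.0408). The 2 knockout comparisons share their WT libraries. Their fold changes had r = 0.526 over all genes, against 0.461 on average in 20 simulations with shared WT and no change. The covariance was 0.153 against 0.0664 simulated. In both, 5 genes rose and 5 fell, all off chromosome 1, where no simulation gave any and independent lists give 0.444 and 0.0487. With 1 WT library for each knockout, split after the values were seen, r was 0.234 and 0.201 for the 2 ways (0.199 and 0.164 off chromosome 1). Then 0 and 4 genes rose and 2 and 3 fell in both.

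In the 24 h experiment interferon genes were higher in SET knockout than in WT cells, averaged over the 2 KH2 lines, and mostly in the SETb line (6 libraries against 6). Ifi27 rose from 0.232 ± 0.434 to 29.7 ± 31.1 CPM (Ifi27 (log2 fold change 6.58 ± 0.57)), and Irgm1, a guanosine triphosphatase of innate defence, from 6.19 ± 4.66 to 105 ± 62 CPM (4.15 ± 0.25). Gbp3 (4.32 ± 0.38), Oasl2 (3.94 ± 0.25), Xaf1 (3.67 ± 0.22) and Usp18 (4.38 ± 0.57) rose with them. Genes of the 2-cell-like state, a rare state that resembles the 2-cell embryo, rose from near 0: Tmem92 (log2 fold change 6.79 ± 0.66), Zscan4d (6.26 ± 0.64), Usp17lb (4.87 ± 0.56) and Usp17le (4.05 ± 0.56). Other large rises were Nxf3 (log2 fold change 4.07 ± 0.33), Robo4 (3.72 ± 0.27) and Pramel6 (3.59 ± 0.30). After Set the largest falls were Gna14 (log2 fold change -3.45 ± 0.54), Rassf6 (-2.89 ± 0.50), Mroh2a (-2.69 ± 0.27), Akap5 (-2.54 ± 0.56), Bcl6 (-2.53 ± 0.32), Zc3h6 (-2.49 ± 0.20) and Zmat4 (-2.42 ± 0.19), where Bcl6 is a transcriptional repressor. Feedback genes of Nodal rose, Lefty1 (2.19 ± 0.19) and Lefty2 (1.65 ± 0.17), and so did Otx2 (1.27 ± 0.14), Egln3 (1.54 ± 0.11) and Slc2a1 (1.37 ± 0.10), the last a glucose carrier. Klf6 (-2.02 ± 0.10), Sox11 (-1.85 ± 0.12) and Peg10 (-1.40 ± 0.13) fell (adjusted p at most 0.00277 over these genes).

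Naive pluripotency genes went both ways. Of 20 measured naive pluripotency genes, 3 rose, 7 fell and 10 were not called (3 rose and 7 fell adjusted over the list alone, adjusted camera p = 0.344, adjusted p = 0.81 with an estimated correlation). Pramel7 rose (Pramel7 (log2 fold change 2.57 ± 0.21)), Dppa3 (-1.19 ± 0.17) and Klf4 (-0.59 ± 0.18) fell, and Nanog (-0.02 ± 0.12), Sox2 (-0.08 ± 0.11), Pou5f1 (0.43 ± 0.20), Zfp42 (0.14 ± 0.11) and Esrrb (-0.39 ± 0.17) were not called (adjusted p at least 0.11). Of 18 measured interferon response genes, 16 rose, 0 fell and 2 were not called (17 rose and 0 fell adjusted over the list alone, adjusted camera p = 5.22e-12, adjusted p = 0.000392 with an estimated correlation). Of 15 measured 2-cell-like genes, 14 rose, 0 fell and 1 was not called (14 rose and 0 fell adjusted over the list alone, adjusted camera p = 5.22e-12, adjusted p = 0.00524 with an estimated correlation). By line, interferon genes had 3 rises and 2 falls in the SETa line and 17 and 0 in the SETb line, and 2-cell-like genes 3 and 14 rises. Over all genes the knockout changes of both lines had r = 0.252, with 112 opposite calls. Of 15 measured Nodal and BMP target genes, 10 rose, 2 fell and 3 were not called (11 rose and 3 fell adjusted over the list alone, adjusted camera p = 0.00348, adjusted p = 0.0977 with an estimated correlation). Of 23 measured glycolysis and hypoxia genes, 8 rose, 0 fell and 15 were not called (9 rose and 0 fell adjusted over the list alone, adjusted camera p = 0.00235, adjusted p = 0.549 with an estimated correlation). Of 20 measured G2 and M phase genes, 0 rose, 12 fell and 8 were not called (0 rose and 13 fell adjusted over the list alone, adjusted camera p = 6.21e-06, adjusted p = 0.122 with an estimated correlation), with Hmmr (log2 fold change -0.94 ± 0.12) and Kif20a (-0.68 ± 0.10) among the falls. Of 43 measured cytosolic ribosomal protein genes, 1 rose and 14 fell (1 rose and 18 fell adjusted over the list alone, adjusted camera p = 0.00348, adjusted p = 0.0797 with an estimated correlation). This includes SETa-line WT libraries 2 and 3, on which some such falls rest after SETa addback. Of 17 measured protein phosphatase 2A genes, 3 rose, 2 fell and 12 were not called (4 rose and 3 fell adjusted over the list alone, adjusted camera p = 0.736, adjusted p = 0.816 with an estimated correlation). Ppp2r2c (log2 fold change 0.81 ± 0.15) and Igbp1 (0.83 ± 0.15) rose and Ppp2r5c (-0.63 ± 0.09) and Ppp2r2d (-0.45 ± 0.12) fell, with Ppp2r2c at -0.00504 in the SETa line alone. The p53 targets Cdkn1a (log2 fold change 0.23 ± 0.13) and Mdm2 (-0.38 ± 0.16) were not called (adjusted p at least 0.0875).

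Fibroblast markers rose beside these groups, with Col3a1 (log2 fold change 2.73 ± 0.32), Prrx1 (2.67 ± 0.40), Fbln2 (1.90 ± 0.15) and Col1a1 (1.65 ± 0.20). Of 20 measured fibroblast (feeder layer) markers, 15 rose, 0 fell and 5 were not called (16 rose and 0 fell adjusted over the list alone, adjusted camera p = 2.08e-08, adjusted p = 0.0797 with an estimated correlation). On the X chromosome 156 of 241 genes of at least 5 log2 CPM rose (median log2 fold change 0.552), among them Rps4x (1.02 ± 0.09). Ddx3y, a gene of the Y chromosome chosen after its values were seen, was 2.59 to 4.33 CPM in WT and 60.7 to 75.5 CPM in knockout libraries of the SETb line. In all 2318 genes rose and 1873 fell of 16305. SETa-line WT libraries 2 and 3, with 2684672 and 528005 counts, stood apart: Pou5f1 was 166 and 161 CPM in them, against 452 CPM in library 1. No single library left out moved the count more than 1.5-fold (range 3340 to 5935).

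Return of SETb for 24 h lowered p53 targets and other genes (2 libraries against 3). The stress gene Ddit4 fell from 318 ± 59.5 to 118 ± 50.7 CPM (Ddit4 (log2 fold change -1.43 ± 0.22)), and Plk2, a kinase induced by p53, from 179.6 ± 33.8 to 62.6 ± 22.9 CPM (-1.52 ± 0.23). The p53 targets Btg2 (-1.47 ± 0.23) and Ccng1 (-0.88 ± 0.15) fell too, and so did Bhlhe40 (-1.46 ± 0.23), Ndrg1 (-1.45 ± 0.24), Bnip3 (-1.23 ± 0.19) and Egln3 (-1.0 ± 0.17), which respond to low oxygen. Further falls were Bc1 (-1.96 ± 0.29), Igdcc4 (-1.47 ± 0.27) and Efnb2 (-1.35 ± 0.22) (adjusted p at most 0.0413). The p53 targets Mdm2 (log2 fold change -0.97 ± 0.25) and Cdkn1a (-0.82 ± 0.21) were lower without a call (adjusted p at least 0.326). Of 24 measured p53 target genes, 0 rose, 3 fell and 21 were not called (0 rose and 12 fell adjusted over the list alone, adjusted camera p = 3.42e-23, adjusted p = 0.00849 with an estimated correlation). Of 19 measured immediate early genes, 0 rose, 1 fell and 18 were not called (1 rose and 6 fell adjusted over the list alone, adjusted camera p = 6.35e-09, adjusted p = 0.0097 with an estimated correlation). Of 23 measured glycolysis and hypoxia genes, 0 rose, 2 fell and 21 were not called (0 rose and 11 fell adjusted over the list alone, adjusted camera p = 8.15e-17, adjusted p = 0.0522 with an estimated correlation). Nanog (log2 fold change 0.28 ± 0.19) and Pou5f1 (0.01 ± 0.31) were not called. In all 3 genes rose, among them Set and Gm9531, and 12 fell of 16305. Without SETb knockout library 2 the calls were 9, without SETb addback library 1 9, without its library 2 2, by DESeq2 63, and 0 when only these groups were fitted. Knockout library 2 and addback library 2 stood apart and were nearest each other (r = 0.9701), and without both the calls were 2. Fibroblast markers had lower values too (median -0.314, 0 of 20 rose and 0 fell).

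Return of SETa for 24 h moved Gm9531 alone (3 libraries against 3, 1 gene called by edgeR of 16305, 338 at unadjusted p under 0.05, DESeq2 2). Fitted with only these groups the count was 205. Egln3, which SETb lowered, was not called (log2 fold change -0.29 ± 0.15), nor were the p53 targets Tnfrsf10b (0.43 ± 0.18), Trp53inp1 (0.24 ± 0.15), Cdkn1a (-0.04 ± 0.18) and Mdm2 (-0.06 ± 0.22) (adjusted p at least 1). Of 15 measured 2-cell-like genes, 0 rose, 0 fell and 15 were not called (0 rose and 0 fell adjusted over the list alone, adjusted camera p = 0.00129, adjusted p = 0.469 with an estimated correlation), with Zscan4e (log2 fold change -2.01 ± 0.91) and Zfp352 (-2.58 ± 1.23). The difference between the 2 addbacks was called for Set alone (Set (log2 fold change -2.53 ± 0.23), adjusted p = 4.55e-05), with 516 genes at unadjusted p under 0.05 and 9 by DESeq2. Plk2 and Ccng1 differed by 1.71 ± 0.30 and 0.99 ± 0.20 without a call (adjusted p at least 0.161). Of 24 measured p53 target genes, 0 rose, 0 fell and 24 were not called (9 rose and 0 fell adjusted over the list alone, adjusted camera p = 6.12e-20, adjusted p = 0.0148 with an estimated correlation). Of 19 measured immediate early genes, 0 rose, 0 fell and 19 were not called (4 rose and 0 fell adjusted over the list alone, adjusted camera p = 5.1e-08, adjusted p = 0.0148 with an estimated correlation).

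The slope of the addback change on the knockout change of the other line was -0.0576 for SETa over 3616 genes and -0.00349 for SETb over 2996 genes. The lines differ in their knockout changes, so a full return would give not -1 but -0.373 for SETa and -0.184 for SETb, from the slope of each line's own knockout change on that of the other, computed after the slopes were seen. Single libraries left out gave -0.0704 to -0.0458 for SETa. The SETb slope was -0.151 without SETb knockout library 2, -0.0923 without SETb addback library 1 and 0.167 without its library 2. It was 0.0288 and 0.0589 without SETb knockout libraries 1 and 3 and 0.000178 without SETa-line WT library 1, and 0.00159 with no filter on low counts, so its direction was not settled.

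SETb addback cells still differed from WT of their line at many genes (2 libraries against 3). Trim30a and Zscan4d, with no count in WT, were at least 81.3-fold and 35.7-fold higher. The interferon genes Rtp4 (log2 fold change 7.59 ± 0.70), Ifi27 (7.36 ± 0.46), Usp18 (7.30 ± 0.55), Oasl2 (6.26 ± 0.36) and Ifit1 (5.78 ± 0.66) rose, and so did Pramel6 (5.81 ± 0.46), Nxf3 (5.74 ± 0.51), Lefty2 (3.13 ± 0.27) and Meis2 (4.12 ± 0.56). The falls were Plac8 (log2 fold change -4.30 ± 0.71), Neurod1 (-3.74 ± 0.71), Tdrd5 (-3.46 ± 0.60), Snai3 (-3.38 ± 0.84), Selenop (-3.10 ± 0.34), Gna14 (-3.06 ± 0.81), Dll1 (-3.04 ± 0.35) and Cldn6 (-2.92 ± 0.37) (adjusted p at most 0.015). Dll1 is a ligand of Notch and Cldn6 a tight junction protein. Of 18 measured interferon response genes, 16 rose, 0 fell and 2 were not called (17 rose and 0 fell adjusted over the list alone, adjusted camera p = 1.96e-20, adjusted p = 2.62e-05 with an estimated correlation). Of 15 measured 2-cell-like genes, 13 rose, 0 fell and 2 were not called (14 rose and 0 fell adjusted over the list alone, adjusted camera p = 1.21e-14, adjusted p = 0.00239 with an estimated correlation). Of 20 measured fibroblast (feeder layer) markers, 12 rose, 0 fell and 8 were not called (15 rose and 0 fell adjusted over the list alone, adjusted camera p = 3.38e-07, adjusted p = 0.122 with an estimated correlation), with Twist2 at least 23.2-fold higher. In all 1649 genes rose and 934 fell. Without WT library 2 of the SETb line the calls were 1687 and without SETb addback library 2 1338.

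SETa addback cells, against WT of their line, had higher Robo4 (log2 fold change 3.51 ± 0.42), Scml2 (3.35 ± 0.30), Slc5a4b (3.15 ± 0.48), Vax2os (2.89 ± 0.47), Otud6a (2.81 ± 0.52), Nhsl2 (2.78 ± 0.55) and Nxf3 (2.67 ± 0.43). Tmem92, with no count in WT, was at least 10.2-fold higher (3 libraries against 3). Lower were the metallothionein Mt2 (-4.43 ± 0.61), the ribosomal protein genes Rpl39 (-3.90 ± 0.74), Rps28 (-3.46 ± 0.71) and Rpl14 (-3.28 ± 0.79) and Hypk (-3.61 ± 0.60), Pax5 (-3.58 ± 0.89) and Atn1 (-3.30 ± 0.70) (adjusted p at most 0.0127). Of 19 measured immediate early genes, 2 rose, 7 fell and 10 were not called (2 rose and 8 fell adjusted over the list alone, adjusted camera p = 0.021, adjusted p = 0.484 with an estimated correlation), with Klf6 (log2 fold change -1.97 ± 0.15) and Jun (-2.12 ± 0.36) among the falls. Of 22 measured imprinted genes, 3 rose, 7 fell and 12 were not called (3 rose and 8 fell adjusted over the list alone, adjusted camera p = 0.186, adjusted p = 0.559 with an estimated correlation). In all 1119 genes rose and 1494 fell. The calls were 5834, 849 and 1649 without WT libraries 1, 2 and 3, 1262, 1329 and 1320 without addback libraries 1, 2 and 3, and 187 when only these groups were fitted. WT libraries 2 and 3 stood apart, and Rpl39 was 29.1 to 644 CPM over WT. Without both, WT is 1 library, taken to vary like the others, and 445 genes were called. Rpl39 then had -0.18, Rpl14 -0.11, Rps28 -0.37, Atn1 -0.58, Pax5 -1.17 and Hypk -2.07, none called, and Mt2 -1.50, still called.

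In the SETa time course at 0 h 4 libraries labelled knockout, of which those of clone 2 kept much Set, were compared with 1 WT library, taken to vary like the other groups. Smc1b rose from 4.27 to 85.2 ± 14.2 CPM (Smc1b (log2 fold change 4.30 ± 0.18)), with the germline genes Tuba3a (2.09 ± 0.10), Piwil2 (1.87 ± 0.14) and Stk31 (2.06 ± 0.17). Other large rises were Slc1a1 (log2 fold change 4.79 ± 0.50), Myl7 (4.53 ± 0.43), Khdc3 (4.19 ± 0.19), Tns4 (4.03 ± 0.40), Grin1 (4.02 ± 0.37) and Ifi27 (3.97 ± 0.40), where Khdc3 serves the early embryo and Grin1 is a glutamate receptor subunit. T, a key factor of the primitive streak, fell from 17.1 to 1.99 ± 1.94 CPM (-3.88 ± 0.26), with the Wnt genes Wnt8a (-3.26 ± 0.26) and Sp5 (-3.02 ± 0.24). Other falls of similar size were Kcnj3 (-4.06 ± 0.27), Slc39a8 (-3.83 ± 0.22), Sema6a (-3.45 ± 0.13), Acta2 (-3.35 ± 0.25), Fst (-3.29 ± 0.19) and Crispld1 (-3.15 ± 0.36). Hand1 and Hnf4a, with no count in WT, were at least 16.7-fold and 12-fold higher. Neural genes fell, Sox11 (-1.53 ± 0.08), Tubb3 (-0.99 ± 0.06), Dll1 (-2.35 ± 0.18), Pax6 (-2.23 ± 0.23), Sox1 (-3.41 ± 0.50) and Nes (-0.64 ± 0.09). Genes of low oxygen rose, Egln3 (2.16 ± 0.11), Ero1l (1.53 ± 0.08) and Pgk1 (1.95 ± 0.12), and so did the naive genes Dppa5a (1.22 ± 0.07), Tbx3 (1.39 ± 0.08) and Tcl1 (1.35 ± 0.09) (adjusted p at most 1.34e-06 over these genes). Nanog (log2 fold change 0.02 ± 0.04), Pou5f1 (0.11 ± 0.05), Sox2 (-0.02 ± 0.05), Klf4 (-0.04 ± 0.06), Zfp42 (-0.02 ± 0.05), Cdkn1a (0.09 ± 0.09), Axin2 (-0.24 ± 0.11) and Gata6 (1.01 ± 0.81) were not called (adjusted p at least 0.0579).

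As groups, of 19 measured germline genes, 17 rose, 0 fell and 2 were not called (17 rose and 0 fell adjusted over the list alone, adjusted camera p = 9e-10, adjusted p = 0.00266 with an estimated correlation). Of 25 measured glycolysis and hypoxia genes, 21 rose, 1 fell and 3 were not called (21 rose and 1 fell adjusted over the list alone, adjusted camera p = 2.08e-09, adjusted p = 0.0334 with an estimated correlation). Of 14 measured neuroectoderm and neuronal markers, 3 rose, 11 fell and 0 were not called (3 rose and 11 fell adjusted over the list alone, adjusted camera p = 0.000198, adjusted p = 0.0294 with an estimated correlation). Of 21 measured imprinted genes, 1 rose, 11 fell and 9 were not called (1 rose and 11 fell adjusted over the list alone, adjusted camera p = 0.000198, adjusted p = 0.0149 with an estimated correlation), with Nnat (log2 fold change -2.54 ± 0.12) and Peg3 (-0.99 ± 0.06). Of 18 measured interferon response genes, 11 rose, 1 fell and 6 were not called (13 rose and 1 fell adjusted over the list alone, adjusted camera p = 0.000459, adjusted p = 0.275 with an estimated correlation). Of 20 measured fibroblast (feeder layer) markers, 1 rose, 16 fell and 3 were not called (1 rose and 16 fell adjusted over the list alone, adjusted camera p = 0.000198, adjusted p = 0.405 with an estimated correlation). Of 20 measured histone chaperones and SET complex genes, 2 rose, 13 fell and 5 were not called (2 rose and 13 fell adjusted over the list alone, adjusted camera p = 0.00218, adjusted p = 0.189 with an estimated correlation), with Hmgb2 (log2 fold change -1.0 ± 0.08) and Nap1l1 (-0.62 ± 0.04). Of 16 measured primitive streak and mesoderm markers, 1 rose, 7 fell and 8 were not called (1 rose and 7 fell adjusted over the list alone, adjusted camera p = 0.0935, adjusted p = 0.275 with an estimated correlation). Of 10 measured definitive endoderm markers, 2 rose, 2 fell and 6 were not called (2 rose and 2 fell adjusted over the list alone, adjusted camera p = 0.96, adjusted p = 0.975 with an estimated correlation), with Sox17 at least 2.63-fold higher. Of 13 measured trophectoderm markers, 4 rose, 2 fell and 7 were not called (4 rose and 2 fell adjusted over the list alone, adjusted camera p = 0.549, adjusted p = 0.666 with an estimated correlation). Of 16 measured Wnt/beta-catenin target genes, 0 rose, 7 fell and 9 were not called (0 rose and 7 fell adjusted over the list alone, adjusted camera p = 0.00525, adjusted p = 0.0842 with an estimated correlation). In all 3681 genes rose and 3531 fell of 17190. The only WT library, with 6293968 counts against 10451604 to 11308432 in the clones, cannot be left out, so its depth and the knockout cannot be told apart at 0 h. At 1 h, with 2 WT libraries of the same depth set as most of the clones, the calls were 9453. Of these 2936 rose and 2992 fell at both times, and 81 went opposite ways. Klf4 and Zfp42, not called at 0 h, had the opposite sign.

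In the SETb time course at 0 h 4 libraries labelled knockout stood against 2 of WT, though clone 2 library 2 was nearest to another line and clone 1 library 2 held 254 CPM of Set against 38.2 CPM in library 1. Otx2 rose from 17.2 ± 1.14 to 81.1 ± 22.8 CPM (Otx2 (log2 fold change 2.23 ± 0.21)). Also raised were Cdh4 (log2 fold change 3.29 ± 0.52), Slc38a5 (3.11 ± 0.28), Grin1 (2.71 ± 0.25), Rtp4 (2.43 ± 0.71), Tgm3 (2.25 ± 0.47), Nhsl2 (2.22 ± 0.50) and Tnfrsf19 (2.16 ± 0.40), where Cdh4 is a cadherin and Slc38a5 an amino acid carrier. Set fell (-2.58 ± 0.45), and so did Rhox5 (-2.29 ± 0.54), Acta2 (-1.83 ± 0.54), Hist1h1c (-1.71 ± 0.19), Anxa3 (-1.68 ± 0.32), Gpnmb (-1.65 ± 0.34) and Dnah10 (-1.58 ± 0.34) and the ribosomal RNA n-R5-8s1 (-2.31 ± 0.65). Genes of cholesterol synthesis rose, Sqle (1.07 ± 0.11) and Hmgcs1 (0.64 ± 0.10), with Pgk1 (0.93 ± 0.17), Ldha (0.48 ± 0.08) and Trh (1.17 ± 0.17) (adjusted p at most 0.0475). Of 20 measured cholesterol synthesis genes, 5 rose, 0 fell and 15 were not called (8 rose and 0 fell adjusted over the list alone, adjusted camera p = 6.36e-06, adjusted p = 0.855 with an estimated correlation). Of 25 measured glycolysis and hypoxia genes, 8 rose, 0 fell and 17 were not called (14 rose and 2 fell adjusted over the list alone, adjusted camera p = 0.00355, adjusted p = 0.855 with an estimated correlation). Of 24 measured p53 target genes, 1 rose, 5 fell and 18 were not called (1 rose and 7 fell adjusted over the list alone, adjusted camera p = 0.0498, adjusted p = 0.855 with an estimated correlation), with Ccng1 (log2 fold change -0.72 ± 0.07) and Btg2 (-0.65 ± 0.10) among the falls. In all 767 genes rose and 678 fell of 16433. Without these 2 and clone 2 library 1 at 2 h, also nearest to another line, 5729 genes were called. The largest falls were then Acsf3 (-5.25 ± 0.34), Eif2s3y (-4.87 ± 0.31), Uty (-4.61 ± 0.33) and Ddx3y (-4.11 ± 0.27), the last 3 on the Y chromosome and chosen after their values were seen. With 1 h in place of 0 h n-R5-8s1 had the opposite sign. The calls were 178 and 238 without WT libraries 1 and 2, 813 without clone 1 library 1, 2240 without clone 2 library 2 and 0 when only these groups were fitted.

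**Figure D4:**
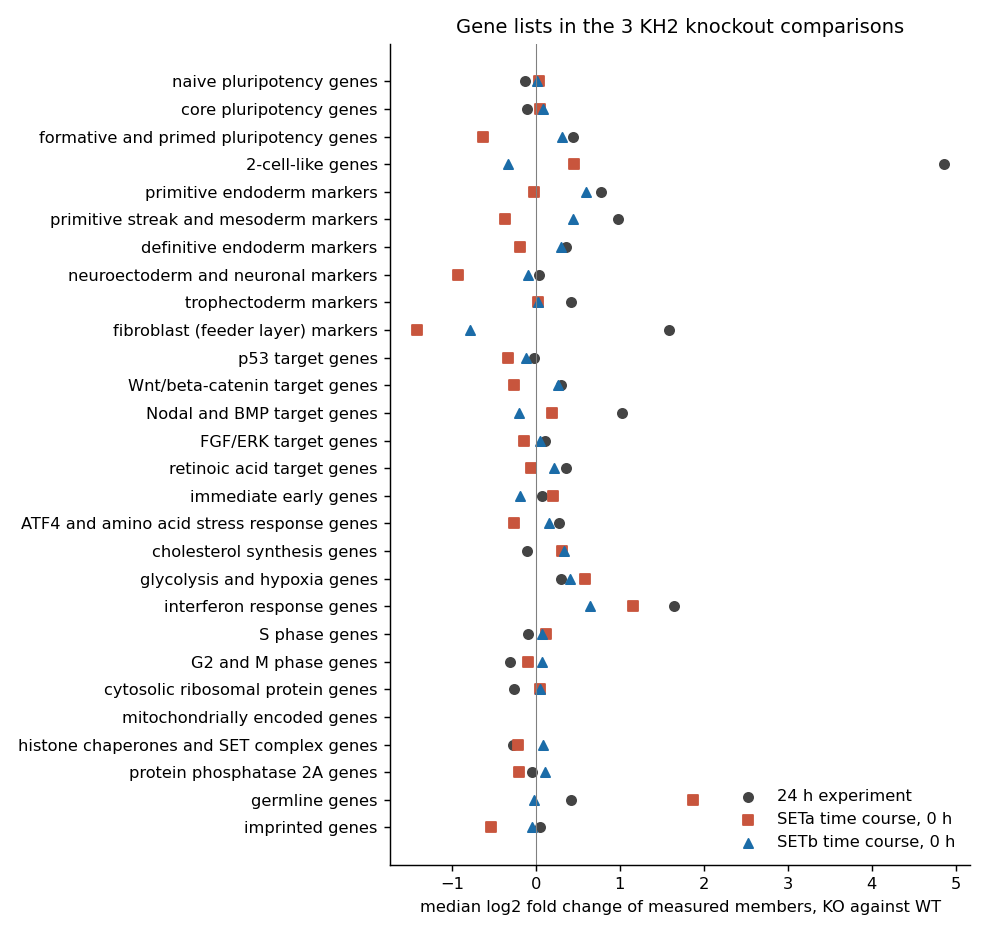
Median log2 fold change of each gene list in the 3 KH2 knockout comparisons. Interferon response genes had 1.65, 1.16 and 0.641 in the 24 h experiment, the SETa and the SETb time course.

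Across the 3 KH2 knockout comparisons 173 genes rose and 81 fell in all, where independent lists give 25.3 and 17.6. At 1 h of the time courses and without the 3 SETb libraries that stood apart, 424 rose and 268 fell in all, against 127 and 121. The shared rises include interferon genes and Otx2. From the lists, Otx2 had log2 fold changes of 1.27 ± 0.14, 1.07 ± 0.09 and 2.23 ± 0.21 in the 24 h experiment, the SETa and the SETb time course, Xaf1 3.67 ± 0.22, 3.05 ± 0.26 and 1.36 ± 0.33, and Egln3 rose in all 3. Chosen after their values were seen, Rtp4 had 6.04 ± 0.86, 2.69 ± 0.48 and 2.43 ± 0.71, Trim30a 5.38 ± 0.74, 2.58 ± 0.65 and 2.89 ± 0.86, Grin1 2.66 ± 0.20, 4.02 ± 0.37 and 2.71 ± 0.25, and the bone protein gene Spp1 fell by 1.09 ± 0.12, 1.09 ± 0.06 and 1.06 ± 0.15. Over all genes the fold changes agreed weakly, with r = 0.213 between the 24 h experiment and the SETa time course, 0.193 with the SETb time course and 0.225 between the time courses. Without those 3 libraries the SETb time course had r = 0.0328 with the 24 h experiment and 0.0290 with the SETa time course. In the latter pair 801 genes rose and 932 fell in both, against 601 and 663 for independent lists, and 1359 went opposite ways. Germline genes went in opposite directions at 1 h: 16 of 19 rose in the SETa time course and 14 of 19 fell in the SETb time course with the 3 libraries left out.

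During 4 h of SETa induction knockout clones changed differently from WT cells at many genes (4 libraries at 4 h and 4 at 0 h in the clones, 2 and 1 in WT). Naive genes rose relative to WT, Nr5a2 (log2 fold change 0.59 ± 0.07), Nr0b1 (0.71 ± 0.09), Tbx3 (0.95 ± 0.12), Esrrb (0.49 ± 0.06), Nanog (0.36 ± 0.05), Klf4 (0.45 ± 0.08) and Zfp42 (0.40 ± 0.07), with the core gene Utf1 (0.67 ± 0.08) and with Zic2 (0.69 ± 0.08). Pax6 (1.43 ± 0.26), Nefm (1.55 ± 0.24), Sall3 (1.49 ± 0.20) and Pou4f2 (1.81 ± 0.37) rose, as did Fgfbp1 (1.94 ± 0.31), Msc (1.63 ± 0.26), Hhip (1.59 ± 0.27) and Sec14l5 (1.53 ± 0.40), where Hhip binds Hedgehog. Of the immediate early genes Fos (log2 fold change -2.11 ± 0.29), Egr1 (-1.07 ± 0.16), Btg2 (-1.06 ± 0.12) and Ier3 (-1.51 ± 0.27) fell relative to WT, while others rose: of 19 measured immediate early genes, 3 rose, 4 fell and 12 were not called (3 rose and 7 fell adjusted over the list alone, adjusted camera p = 0.135, adjusted p = 0.454 with an estimated correlation). Fos rose in WT from 0 to 4 h by 1.32 ± 0.26 and fell in the clones by 0.79 ± 0.14. Gm9531 rose in WT too, by 0.56 ± 0.10 at 4 h, so if the WT cells hold the transgene the difference takes off part of the induction. Other falls were Rn7sk (log2 fold change -2.96 ± 0.74), Stc1 (-2.57 ± 0.32), Myl7 (-2.38 ± 0.71), Rpl32l (-2.21 ± 0.39), Snrpf (-2.09 ± 0.32), Rps7 (-1.99 ± 0.29) and Ppp1r3b (-1.93 ± 0.37). Smaller falls were Egln3 (-0.77 ± 0.18), Vegfa (-0.81 ± 0.23) and Otx2 (-0.54 ± 0.12) (adjusted p at most 0.0222 over these genes). Of 20 measured naive pluripotency genes, 12 rose, 1 fell and 7 were not called (12 rose and 1 fell adjusted over the list alone, adjusted camera p = 3.42e-08, adjusted p = 0.0377 with an estimated correlation). Of 14 measured core pluripotency genes, 7 rose, 0 fell and 7 were not called (8 rose and 0 fell adjusted over the list alone, adjusted camera p = 8.64e-05, adjusted p = 0.106 with an estimated correlation). Of 23 measured ATF4 and amino acid stress response genes, 10 rose, 1 fell and 12 were not called (14 rose and 2 fell adjusted over the list alone, adjusted camera p = 5.9e-05, adjusted p = 0.0586 with an estimated correlation), with Atf4 (log2 fold change 0.56 ± 0.07) and Mthfd2 (0.75 ± 0.10) up and Ddit4 (-0.74 ± 0.11) down. Of 25 measured glycolysis and hypoxia genes, 0 rose, 7 fell and 18 were not called (0 rose and 9 fell adjusted over the list alone, adjusted camera p = 0.00731, adjusted p = 0.423 with an estimated correlation). In all 1321 genes rose and 811 fell of 17190. Without WT library 1 at 4 h the calls were 1229, by DESeq2 1355, and the only WT library at 0 h cannot be left out. Between 0 and 4 h the clones, unlike WT, went from a deeper to a shallower set of libraries, and this difference, taken in WT, had r = 0.474 with the step of the clones from 1 to 2 h. From 1 to 4 h WT and clones both crossed the sets. With that baseline, chosen after the data were seen, 1882 genes were called, with 1056 of the calls from 0 h kept in direction, and 13 of 20 naive genes rose. With 1 h in place of 4 h 503 genes were called, and Nanog, Ppp1r3b and Egr1 had the opposite sign, as had Egr1 at 2 h.

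SETb induction gave no called gene at 4 h (3 libraries at 4 h and 4 at 0 h in the clones, 2 and 2 in WT, 0 of 16433 by edgeR, 745 at unadjusted p under 0.05, DESeq2 0). The smallest p-values belonged to Pstpip2 (log2 fold change -1.70 ± 0.35), Mep1b (1.58 ± 0.35) and Tmem106a (-0.87 ± 0.20) (adjusted p at least 0.901). Nanog, Klf4 and Esrrb had 0.03 ± 0.16, 0.17 ± 0.23 and 0.30 ± 0.34, and the p53 targets Cdkn1a (log2 fold change 0.16 ± 0.31) and Mdm2 (0.22 ± 0.25) were not called. Of 44 measured cytosolic ribosomal protein genes, 0 rose, 0 fell and 44 were not called (0 rose and 0 fell adjusted over the list alone, adjusted camera p = 1.04e-06, adjusted p = 0.936 with an estimated correlation). With the 3 libraries that stood apart left out, 31 genes were called.

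Added SETa in cells that kept their own SET gave no called gene after 24 h (2 libraries against 3, 0 of 17873 by edgeR, 285 at unadjusted p under 0.05, DESeq2 31, 7 when only these groups were fitted). The smallest p-values were those of Gm9531 (log2 fold change 0.56 ± 0.10), Amotl2 (0.38 ± 0.08) and Prpf38b (-0.29 ± 0.07) (adjusted p at least 1). Nanog (log2 fold change -0.02 ± 0.10), Pou5f1 (-0.03 ± 0.14), Sox2 (0.04 ± 0.09), Klf4 (-0.04 ± 0.15) and Esrrb (0.10 ± 0.14) lay near 0. Of 20 measured histone chaperones and SET complex genes, 0 rose, 0 fell and 20 were not called (0 rose and 0 fell adjusted over the list alone, adjusted camera p = 0.00562, adjusted p = 0.967 with an estimated correlation), with Anp32a (log2 fold change -0.23 ± 0.08) and Hmgb2 (-0.28 ± 0.13). Planted 2-fold changes were called in 20% and 4-fold changes in 61% of genes for this comparison.

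After 24 h of added SETb collagen genes were among the rises and pluripotency genes among the falls (3 libraries against 3). Col1a1, the main collagen, rose from 256 ± 228 to 10210 ± 2066 CPM (Col1a1 (log2 fold change 5.32 ± 0.60)), and Itga11, a collagen receptor, from 2.08 ± 0.282 to 329 ± 68.6 CPM (7.29 ± 0.25). Ankrd1 (8.25 ± 0.43), Clstn2 (8.15 ± 0.82), Scg2 (8.47 ± 0.87), Gdf5 (7.49 ± 0.50), Arsj (7.33 ± 0.95), Cntn4 (6.84 ± 0.97) and Ano4 (6.82 ± 0.67) rose from under 1 CPM. Ccn1 and Ccn2, which answer stretch and YAP, rose (3.24 ± 0.16 and 2.94 ± 0.25), as did Col4a1 (2.88 ± 0.24), Nes (1.33 ± 0.10), Junb (1.89 ± 0.13) and Dusp4 (1.60 ± 0.12). Hand1 fell (-7.58 ± 1.79), and so did Krt19 (-3.43 ± 1.01), Rbm47 (-1.52 ± 0.30), Rab25 (-1.48 ± 0.29) and Esrp2 (-1.45 ± 0.35), Eomes (-1.60 ± 0.31), Ankrd37 (-1.42 ± 0.20) and Egln3 (-1.38 ± 0.15). The pluripotency genes fell as well, with Nanog (-0.67 ± 0.09), Klf4 (-0.67 ± 0.13), Zfp42 (-0.63 ± 0.13), Pou5f1 (-0.65 ± 0.12), Esrrb (-0.46 ± 0.13), Sox2 (-0.40 ± 0.08) and Tdgf1 (-0.85 ± 0.12) (adjusted p at most 0.0288 over these genes). Set, Mdm2 (-0.15 ± 0.10) and Cdkn1a (-0.26 ± 0.17) were not called, with Set at -0.04 ± 0.09.

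Of 20 measured naive pluripotency genes, 1 rose, 17 fell and 2 were not called (1 rose and 18 fell adjusted over the list alone, adjusted camera p = 3.69e-06, adjusted p = 0.444 with an estimated correlation). Of 14 measured core pluripotency genes, 0 rose, 13 fell and 1 was not called (0 rose and 14 fell adjusted over the list alone, adjusted camera p = 1.82e-07, adjusted p = 0.412 with an estimated correlation). Of 20 measured G2 and M phase genes, 0 rose, 20 fell and 0 were not called (0 rose and 20 fell adjusted over the list alone, adjusted camera p = 2.74e-08, adjusted p = 0.412 with an estimated correlation). Of 20 measured S phase genes, 0 rose, 17 fell and 3 were not called (0 rose and 19 fell adjusted over the list alone, adjusted camera p = 1.51e-07, adjusted p = 0.412 with an estimated correlation). Of 18 measured fibroblast (feeder layer) markers, 10 rose, 0 fell and 8 were not called (10 rose and 0 fell adjusted over the list alone, adjusted camera p = 3.2e-05, adjusted p = 0.444 with an estimated correlation). Of 19 measured immediate early genes, 12 rose, 3 fell and 4 were not called (13 rose and 4 fell adjusted over the list alone, adjusted camera p = 0.00321, adjusted p = 0.412 with an estimated correlation). Fibroblast markers held 1.20 to 1.65% of counts with SETb, 0.0664 to 0.290% in controls of the line and 0.0600 to 0.0667% in controls of the SETa line. In all 3035 genes rose and 3101 fell of 17873. The calls were 3452, 12319 and 3472 without control libraries 1, 2 and 3, 3530 and 3329 without SETb libraries 2 and 3, and 1761 when only these groups were fitted. With the share of fibroblast markers as a covariate, 3560 genes were called and Nanog, Klf4, Zfp42, Pou5f1, Esrrb and Tdgf1 turned direction.

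**Figure D5:**
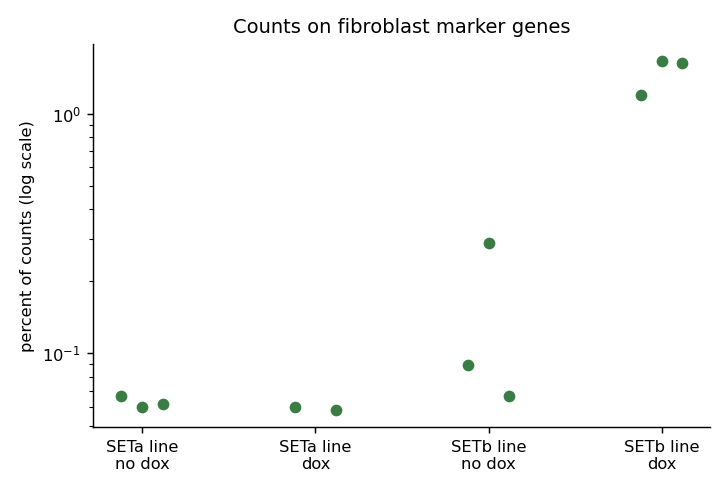
Percent of counts on 20 fibroblast markers in each overexpression library. The range was 1.20 to 1.65% with SETb and 0.0664 to 0.290% in controls of the SETb line.

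The changes after SETa and SETb overexpression were compared by their difference. Relative to SETb, SETa left Foxd3 (log2 fold change 1.45 ± 0.26), Tcf15 (1.29 ± 0.24), Olig1 (1.31 ± 0.29), Espn (1.26 ± 0.29), Cyp2s1 (1.26 ± 0.14), Zdhhc23 (1.20 ± 0.22), Egln3 (1.24 ± 0.22) and Ankrd37 (1.20 ± 0.29) higher, where Foxd3 and Tcf15 guide exit from pluripotency. Lower were Ankrd1 (-8.91 ± 0.96), Itga11 (-8.31 ± 0.42), Cntn4 (-8.27 ± 2.08), Gdf5 (-8.14 ± 0.82), Tgfb2 (-7.66 ± 1.40), Ano4 (-7.17 ± 1.40), Prss23 (-6.32 ± 0.56) and Igfbp5 (-6.27 ± 1.07). So were Col1a1 (-5.43 ± 0.84), Ccn1 (-3.09 ± 0.24) and Nes (-1.35 ± 0.15). Tgfb2 and Igfbp5 are secreted by fibroblasts and other cells. Nanog (0.64 ± 0.14) and Dnmt3b (0.76 ± 0.08) were higher, while Pou5f1 (0.61 ± 0.18), Sox2 (0.44 ± 0.12), Klf4 (0.63 ± 0.20), Zfp42 (0.67 ± 0.19) and Esrrb (0.56 ± 0.19) were not called (adjusted p at least 0.0633, against adjusted p at most 0.0499 for the others). In all 288 genes were higher and 869 lower (5 and 6 libraries). Without SETa control libraries 1, 2 and 3 the calls were 485, 484 and 537, without SETa libraries 1 and 2 163 and 201. Without SETb control libraries 1, 2 and 3 they were 575, 9112 and 546, and without SETb libraries 2 and 3 450 and 474. With the share of fibroblast markers as a covariate Nanog and Ankrd37 turned direction, and DESeq2 called 2766 genes.

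Mitochondrially encoded genes had 0 measured members in every experiment, since the deposited counts hold 0 reads on them, for a reason not given in the labels.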

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

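The tests of an extra chromosome 1, of isoform loss, of RNA from other cells, of feeder fibroblasts, of the transgene at Col1a1, of sets that differ in depth and of the calls from 1 h were chosen only after the results were seen. The other tests and their bounds were written before their values were seen, and 1 of these bounds, on SETb and fibroblast markers, was later replaced.

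The changes after SETa and SETb overexpression differed at 1157 genes, and those after the addbacks at 1 gene. The knockout change differed between the SETa and the SETb line of the 24 h experiment at 1889 genes. The change over 4 h of SETa induction differed between both clones at 9 genes, and the R1 knockouts of SETa and SETb at 111 genes. In the WT library at 0 h of the SETa time course that was left out for its depth, A2m held 252 CPM, against at most 45.9 CPM in the other WT libraries. A test for a single far value in Set, Gm9531, Pou5f1, Nanog or total counts was possible only in the R1 groups, where 0 of 15 sets held one. Their files are lanes of 2 libraries per group, so it does not show the spread between samples. It does not cover control library 2 of the SETb overexpression line, which differed from libraries 1 and 3 with chi-square per degree of freedom of 68.5 and 60.5, against 2.41 between these.

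For the 24 h knockout 1 of 100 splits of the libraries, the real one, gave as many calls (3461, highest other 1167), which argues against a random grouping of libraries as the source. Splits were too few for a share under 0.05 elsewhere: 1 of 10 for SETa addback (205, highest other 1), 1 of 10 for SETa addback against WT (187, highest other 0) and 1 of 10 for SETb overexpression (1761, highest other 0).

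Genes on chromosome 1 were higher in both R1 knockouts. The tables argue against 1 WT library out of line, since the lowest knockout share of counts on chromosome 1 lay 2.21 percentage points above the highest WT share. They argue against loss of a SET isoform as the source, since the highest chromosome 1 median in the KH2 knockouts was 0.0887. A candidate explanation is an extra copy of chromosome 1 in part or all of the knockout cells: the lower of both medians over all tested genes was 0.492 and the lowest over stretches of the chromosome 0.456. This stays a hypothesis, found and tested on the same libraries.

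Fibroblast markers rose with SETb overexpression, and 17 of 20 markers had at least 1 CPM in the SETa line without doxycycline (0 held by another list). Counts from a transgene at Col1a1 would leave the other markers in place, but their median change was 1.19. Feeder fibroblasts as seen in the 24 h experiment would bring all their transcripts, but 4 of 19 markers reached 0.25 of that rise, of which Mmp2 did not rise there (by library totals, Col1a1 9460, Col1a2 1200 and Col5a1 1160 CPM, but Dcn 6.84 and Prrx1 10.5 CPM). RNA of another kind of cell may be present: the 28 naive and core pluripotency genes of at least 5 log2 CPM fell together (median -0.774 without control library 2), with a spread beyond their standard errors of 0.147 log2 units, refitted after the value of 0.105 (median -0.601) with all libraries. SETb itself and these cells cannot be told apart here: on SETb addback the markers had a median of -0.314, and among controls the highest share was 4.36 times the lowest, which meets the bound written beforehand against SETb. That bound was replaced after the value was seen, because addback cells lack their own SET, spread among controls does not forbid induction, and all 3 SETb libraries (1.20 to 1.65%) lay above all 3 controls (0.0664 to 0.290%).

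Many genes were called at 4 h of SETa induction. GC content does not account for them (r = -0.0258 across genes, 100% with a value), nor does a split by time, since the step from 1 h to 2 h in WT and clones had r = 0.109 (0.159 over called genes). Libraries fell instead into a deeper set (WT at 1 and 2 h, clones at 0 and 1 h, though 1 clone 1 library at 1 h held 5773714 counts) and a shallower set (WT at 0 and 4 h, clones at 2 and 4 h, 4139935 to 6422389 counts). The difference between the sets in WT and the step from 1 h to 2 h in the clones had r = 0.474 (0.636 over genes of at least 5 log2 CPM), and the contrast from 0 h follows the sets. With 1 h as the baseline WT and clones both cross them and the single WT library at 0 h is not used, yet 1882 genes were called, 1056 of them among the 2132 and in the same direction. That library and an effect of the sets of equal size in WT and clones drop out with this baseline, so the count tests neither. For genes called from 0 h alone the sets, that library and SETa cannot be told apart, as that contrast confounds them. An effect of the sets that differs between WT and clones, and induction of SETa, stay open.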

How the results depend on the processing

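The 21 alternatives described with the processing were chosen after the data were seen. The others were fixed before. Except where stated the cause of a change was not tested. Scaling by RLE factors kept every count of calls within 1.5 times. R1 libraries held 368270 to 1111486 counts and only 2 libraries stood in a group.

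For loss of SETa in R1 (22 calls) the count was 70 with no filter on low counts, 13 by DESeq2, and 1 to 29 with 1 library left out. With the 16 files taken as replicates, which counts lanes of 1 library as separate samples, it was 488, and 401 with the replicate number as a block. For loss of SETb (328) the same settings gave 800 and 666. DESeq2 gave 105, calls off chromosome 1 and the chromosome 14 segment 218, and 1 library left out 126 to 355. Between the knockouts (111) no filter gave 199, the 16 files 351 and 271, DESeq2 67, calls off those regions 66 and 1 library left out 36 to 91.

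In the 24 h experiment the knockout count (4191) ranged over 3340 to 5935 with 1 library left out. SETa addback (1) gave 9 with no filter, 2 by DESeq2, 205 with the compared groups alone and 1 with any library left out. SETb addback (15) gave 38, 63 and 0 under these settings. It gave 2 without the second libraries of both groups and 2 to 14 with 1 library left out. Their difference (1) gave 14 with no filter, 2 with a replicate block, 9 by DESeq2 and 1 to 3 with 1 library left out. SETa addback against WT (2613) gave 187 with the compared groups alone, 445 without WT libraries 2 and 3 and 849 to 5834 with 1 library left out. SETb addback against WT (2583) gave 1594 without the second knockout libraries and 1338 to 2030 with 1 library left out. The rescue slope of SETa was -0.0775 on the genes of the other time course and -0.0704 to -0.0458 with 1 library left out, and that of SETb -0.151 to 0.167. The latter turned above 0 in the settings given above.

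In the SETa time course the knockout count (7212) ranged over 6884 to 7056. SETa induction (2132) gave 1355 by DESeq2, 8323 where the WT change was not taken off, 503 at 1 h and 1229 to 2283 with 1 library left out. In the SETb time course the knockout count (1445) was 0 with the compared groups alone, 720 for clone 2 alone, and 2800 at 1 h. It was 5729 without the 3 libraries that stood apart and 178 to 2240 with 1 library left out. SETb induction (0) gave 168 with no filter, 2467 where the WT change was not taken off, 31 without the 3 libraries and 0 with any 1 left out (edgeR, 745 at unadjusted p under 0.05, DESeq2 0). SETa overexpression (0, 285 at unadjusted p) gave 31 by DESeq2, 7 with the compared groups alone and 0 with any 1 library left out. SETb overexpression (6136) gave 1446 with the low-depth library put back, 1761 with the compared groups alone. It gave 3560 with the fibroblast share as a covariate, 12319 without control library 2 and 3329 to 12319 with 1 library left out. The difference of the isoforms (1157) gave 727 with no filter, 260 with the library put back, 733 with a replicate block. It gave 2766 by DESeq2, 1798 with the covariate, 9112 without that control library and 163 to 9112 with 1 library left out. Leaving out the only WT library at 0 h of the SETa time course, or the only clone 1 library at 4 h of the SETb time course, was not possible.

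Over the named genes 5132 values kept direction and side of the threshold, 477 lost and 66 gained a call in the same direction, 75 moved without a call and 20 reversed. The reversed log2 fold changes were Ppp2r2c -0.00504 in the SETa line alone, Klf4 0.11, Zfp42 0.12 at 1 h of the SETa time course, and n-R5-8s1 0.60 at 1 h of the SETb time course. For SETa induction they were Nanog -0.0176, Ppp1r3b 0.36, Egr1 0.41 at 1 h, Egr1 0.36 at 2 h and Egr1 0.12 where the WT change was not taken off. With the covariate, which nearly coincides with doxycycline, SETb overexpression gave Set 0.62, Klf4 0.35, Nanog 0.00491, Mdm2 0.60, Zfp42 0.26, Tdgf1 0.0132, Esrrb 0.52, Cdkn1a 1.02, Pou5f1 0.32, and the difference Nanog -0.0447, Ankrd37 -0.0307.

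The replicate numbers did not pair the libraries: same-numbered deviations correlated above 0.1 in 2 of 6 pairs in R1, 6 of 40 in the 24 h experiment, 0 of 90 and 2 of 90 in the time courses and 1 of 15 on overexpression. A block on library order in R1 gave 16, 297 and 97 calls. Elsewhere the replicate block gave 4244 for the 24 h knockout, 1 and 17 for the addbacks and 2798 and 2464 against WT. It gave 7139 and 1231 for the time-course knockouts, 2110 and 0 for the inductions, and 0 and 5589 on overexpression.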

Other observations

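Egr1 and Fos, both immediate early genes, rose in WT cells of the SETa time course too. At 1 h of the SETa time course Egr1 had a log2 fold change of 1.59 ± 0.13 in WT and 2.00 ± 0.06 in the clones, and Fos of 1.36 ± 0.25 and 1.23 ± 0.09 (edgeR). At 4 h Egr1 was still 1.19 ± 0.14 above its level at 0 h in WT, but 0.12 ± 0.08 and not called in the clones. The WT values rest on 1 library at 0 h. In the SETb time course the clones had 1.09 ± 0.14 for Egr1 and 0.98 ± 0.16 for Fos at 1 h, while WT had 0.78 ± 0.20 for Egr1, not called. Later both fell there, at 2 h by 0.69 ± 0.14 and 0.80 ± 0.16 in the clones, and at 4 h Fos fell in WT by 1.44 ± 0.24. Egr1 and Fos are early targets of growth factor signalling, and handling of the cells was not tested. The genes, libraries and comparisons of this part were chosen after the values were seen, apart from the slopes of the time courses.

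Without the 3 libraries of the SETb time course that stood apart, SETb induction raised Set (log2 fold change 1.10 ± 0.12), Tubb3 (0.71 ± 0.10), Prdm14 (0.78 ± 0.16), a naive factor, and Lefty1 (0.54 ± 0.10), and lowered Ccnd2 (-0.43 ± 0.09) and Ccne1 (-0.33 ± 0.07), cyclins of entry into S phase. At 1 h of that time course, without these libraries, 30 of 44 ribosomal protein genes rose and 4 fell in the knockout (adjusted camera p = 0.000312, adjusted p = 0.401 with an estimated correlation). In the SETa time course at 1 h 16 fell and 2 rose, not called as a list (adjusted camera p = 0.093, adjusted p = 0.405 with an estimated correlation). With SETb overexpression and control library 2 left out, 15 of 18 neuroectoderm and neuronal markers rose and 3 fell (adjusted camera p = 0.00907, adjusted p = 0.419 with an estimated correlation). In it 38 of 44 ribosomal protein genes fell and 2 rose (adjusted camera p = 1.34e-06, adjusted p = 0.141 with an estimated correlation). Of glycolysis and hypoxia genes 21 of 25 fell and 3 rose (adjusted camera p = 1.28e-05, adjusted p = 0.231 with an estimated correlation).

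Ddx3y, on the Y chromosome, differed between groups of the same line. It was 42.9 to 49.1 CPM in WT, 12.6 to 14.3 in clone 1 and 0.199 to 3.13 in clone 2 at 1 h of the SETb time course. At 0 h of the SETa time course it was 79.6 to 87.2 CPM in clone 1 and 30.3 to 32.2 in clone 2, and it ranged from 3.88 to 61.6 CPM over the controls of the SETb overexpression line. X-linked genes had a median log2 fold change of 0.259 in the SETa and 0.460 in the SETb time-course knockout, where chromosome 11 had -0.275.

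The library labelled clone 2, 0 h, replicate 2 of the SETb time course held 37352955 counts and was nearest to a clone 1 library of the SETa time course (r = 0.9925 across 7880 genes, against a median of 0.9369 within its line). The library labelled clone 2, 2 h, replicate 1 was nearest to clone 2 at 2 h of the SETa time course (r = 0.9883 against 0.929). Genes are not independent replicates.

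Whether induction of SETa moves knockout-changed genes towards WT within hours stays open. The slope of the change from 1 h to 4 h in the clones on the knockout change at 0 h was -0.231, but WT cells had -0.150, over 0.5 of that slope. At 0 h deeper clone libraries were set against 1 shallower WT library. From 1 h to 4 h clones and WT both went mostly from deeper to shallower libraries. A difference between these sets alone would give a negative slope in both, so the sign does not show a return towards WT. For SETb, without the 3 libraries, slopes were -0.0125 in clones and -0.0267 in WT. Such a move stays open, as Gm9531 at 4 h was 156 to 187 CPM in clones (WT 523 to 549).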
